A study of Mus musculus with 31 samples.

How the data were processed

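Gene expression was measured in skin of C3H/HeJ mice on 31 Affymetrix arrays. Per the labels' protocols, total RNA was extracted with the Qiagen miRNeasy kit including a DNase step on the column, and biotin-labelled targets were made with the Affymetrix kit for 3' in vitro transcription. The authors processed the arrays with RMA, per the submitters' processing notes, which corrects background, equalises the distributions of the arrays and summarises the probes of each probe set. The deposited table holds log2 RMA values of the authors, and its range of 2.59 to 14.69 and array medians of 6.05 to 6.24 were checked on the values. The RMA version is not given in the sources used here, and the table held no missing value. Detection calls and scan dates were not used here, so a scanning batch was not tested.

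The labels give 3 arms, named PBS, jak1i and jak3i, and a treatment time that was read as weeks because the sample titles carry a W. Each arm has 3 arrays at 0, 6 and 12 weeks, and the inhibitor arms have 2 arrays each at 24 weeks, which makes 11 groups. PBS at 24 weeks was not analysed here. The compounds are known only by their codes and no dose is given in the sources used here. The series text calls the replicates biological, and whether the same mice were sampled over time is not stated. All p-values therefore measure the spread between these samples.

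Of 45101 probe sets, 64 were array controls. A probe set was assigned to a gene where the probe table named 1 symbol, which held for 34958, while 932 named several symbols and 9211 named none. The Entrez identifier matched the reference gene table for 34741 of the single-gene probe sets, and no symbol was changed. The 34945 probe sets of 1 gene that were no controls covered 18193 genes, of which 9183 had 1 probe set and 9010 had more. For the latter the probe set with the highest mean over the 31 arrays stood for the gene. The probe sets without a single gene name were tested apart.

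Comparisons were made with limma 3.58.1 in R 4.3.3. A single linear model with 11 group means was fitted to the log2 values of the 31 arrays, with 20 residual and 2.50 prior degrees of freedom for the moderated test, and each comparison was a contrast of these means. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The comparison of either inhibitor with PBS used 10 group means. There were 20 planned contrasts, and 8 more, which are named where they are used, were chosen after the data had been seen. Errors are standard errors of the fitted difference, and intervals are 95% intervals.

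For gene groups, 35 lists of pathways and cell types were used. Each was tested with camera at a preset correlation between genes of 0.01, and beside it with the correlation estimated for each list, and with fry. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move one way, or in its mixed form in either direction, without a comparison with other genes. Members past the threshold were counted over all genes and adjusted over the list alone. A list mean is the mean over its members of the log2 value relative to the mean of the 31 arrays, and its differences between groups come from an ordinary linear model of the 11 groups. The lists, the 20 contrasts, the tests, the rule for named genes and the first set of other settings below were fixed before the data were examined.

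By that rule, the main comparisons (each inhibitor at 12 weeks against PBS at 12 weeks, and against its own arm at 0 weeks) name the 10 largest rises and the 10 largest falls among changed genes whose compared groups did not overlap. Other contrasts name the 3 largest in each direction, or the genes with the smallest p where none passed. For every list the 4 members with the largest change in a main comparison are named, along with a fixed set of kinase, interferon, cytotoxic and hair genes, and gene models without a name were skipped. This gave 304 genes. Where several probe sets measured a named gene of a main comparison, 13 of 119 pairs of gene and contrast (59 genes) had probe sets of opposite sign, and in 0 of them were probe sets called in opposite directions.

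The other settings fixed in advance were centring each array on its median, leaving out dim genes (fewer than 2 arrays above the median of all values, 6.177), the mean of all probe sets of a gene, a trended and robust variance, a fit to the compared arrays only, the replicate number as a fixed term, the arm and number as a random block, and leaving out each array in turn. PBS at 6 weeks as the control, the hair shaft list mean as a covariate and the skeletal muscle list mean as a covariate were added after the data had been seen, and so was leaving out arrays in the shared genes (and both covariates there) and in the list means of jak1i against jak3i. Their effects stand in the closing section. Replicate numbers were checked for pairing by correlating the deviations of same-numbered arrays from their group means. In 3 of 36 pairs of groups all 3 correlations were over 0.1, among them jak3i and PBS at 12 weeks (0.164, 0.201 and 0.382). The median over all was −0.024, with a range of −0.609 to 0.626.

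The procedure was tested on values drawn for each gene apart around its mean with its residual spread. At each of 4 sizes 50 of 18193 genes were changed. At a log2 change of 0.50, 1, 2 and 3, limma recovered 48%, 74%, 94% and 98% of the changed genes for jak1i against PBS at 12 weeks, with 11 false among 168 calls. For jak3i against PBS it recovered 52%, 72%, 96% and 98% (13 false of 172), for jak1i at 12 against 0 weeks 54%, 74%, 96% and 98% (8 of 169), and for jak3i 36%, 74%, 94% and 98% (8 of 159). The list test recovered 1 of 1 shifted list and called 0 others, but genes drawn apart cannot test the preset correlation. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.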

Results

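Skin of C3H/HeJ mice with AA, read here as alopecia areata, was compared between 3 topical arms, PBS, jak1i and jak3i, at 0, 6 and 12 weeks (3 arrays each), with 2 arrays each of jak1i and jak3i at 24 weeks. At 0 weeks the gene lists of cytotoxic lymphocytes, of the interferon-γ response and of the hair shaft stood above the mean of the 31 arrays in every arm. Under both inhibitors the cytotoxic genes Gzma and Gzmb and the chemokine gene Ccl5, which draws T cells, fell by 6 and by 12 weeks, and genes of the interferon-γ response such as Cxcl11 and Tap1 fell with them. From 0 to 12 weeks fat cell genes rose in 10 of 15 in jak1i and 2 in jak3i, sebaceous genes in 7 and 2 of 15 and endothelial genes in 4 and 10 of 16. Hair shaft genes fell in 0 of 45 in jak1i (median −4.25) and 23 in jak3i (median −5.23). With the hair shaft mean as covariate, chosen after seeing the data, 0 fat cell, sebaceous and endothelial genes rose. Then 10 cytotoxic and 6 interferon-γ genes fell in jak1i and 0 in jak3i. No list of these comparisons was called with an estimated correlation. Values below are log2 differences, with the standard error and adjusted p of limma in brackets. They compare groups of 3 arrays unless 24 weeks is named. The largest changes are taken among changed genes whose compared groups did not overlap.

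At 0 weeks, before treatment, no gene separated jak1i from PBS or jak3i from PBS in limma. The granule genes Gzma and Gzmb and the T cell gene Cd8a stood in jak1i at −0.42 (0.71, 0.999), 0.39 (0.73, 0.999) and −0.11 (0.29, 0.999). In jak3i they lay at −1.44 (0.71, 0.669), −0.43 (0.73, 0.972) and −1.12 (0.29, 0.418), and the killing ligand gene Fasl at −1.85 (0.37, 0.391). The smallest adjusted p was 0.983 for jak1i and 0.149 for jak3i, the latter for Ccdc126 −0.60. The counts were 0 and 0 of 18193 genes, with 917 and 1378 genes under an unadjusted p of 0.05, and leaving out PBS at 0 weeks replicate 1 gave 4 genes for jak3i. The T cell list of 19 genes had a median of −0.42 in jak3i against PBS, with 7 members past the threshold over the list alone and 0 over all genes (camera adjusted p = 9.6e-11, adjusted p = 0.370 with an estimated correlation). The cytotoxic T and NK cell list lay at −0.41 with 4 of 21 members lower over the list alone (camera adjusted p = 7.9e-07, adjusted p = 0.701 with an estimated correlation). Its list mean differed by −0.535 (95% interval −1.124 to 0.055), which leaves a lower start open. T cell list means of jak3i (−0.167 to 0.237) all lay below PBS (0.258 to 0.640).

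In the PBS arm the named interferon and cytotoxic genes did not pass the threshold over time. From 0 to 12 weeks, with n = 3 each, Gzmb moved by −0.44 (0.73, 0.831), Cxcl9 by 0.06 (1.07, 0.986) and Cd8a by −0.46 (0.29, 0.468), and the hair shaft gene Krtap15 by 0.53 (1.73, 0.921). What fell were skeletal muscle genes. The sarcomere genes Neb −5.63 (0.75, 3.9e-04), Klhl41 −5.39 (0.68, 3.6e-04) and Myot −5.20 (0.78, 0.00105) had the largest falls, and 18 of 20 muscle genes fell, also over the list alone (median −3.78, camera adjusted p = 2.8e-40, adjusted p = 0.0194 with an estimated correlation). The largest rises were Wfdc12 2.19 (0.54, 0.0357), Pou2af1 1.46 (0.31, 0.0133) and Nt5dc2 1.29 (0.31, 0.0301). The macrophage list lay higher by a median of 0.76 (camera adjusted p = 0.0158), the mast cell list by 0.89 (camera adjusted p = 0.0158) and the cell cycle list by 0.56 (camera adjusted p = 1.7e-04), each with 0 members past the threshold over all genes and an adjusted p = 0.970 with an estimated correlation. In all, 414 of 18193 genes changed, 253 higher and 161 lower, of which 10 and 112 at least 2-fold, and 413 of the 414 had groups without overlap against 23.9% of all genes and 10% by chance. After centring the arrays on their medians 242 genes passed, 81 higher and 161 lower, and 165 passed in a fit to the compared arrays. Without PBS at 0 weeks replicate 1 or 2 the count was 83 or 103, and without PBS at 12 weeks replicate 1 or 3 it was 150 or 164. From 0 to 6 weeks 1 gene changed, Snhg12 0.74 (0.11, 0.018) (unadjusted p under 0.05 in 1786 genes), which lost its call with each PBS array at 0 weeks left out in turn. That count became 4, 2 and 0 without PBS at 6 weeks replicate 1, 2 and 3, 0 with the compared arrays alone and 3 with the mean of probe sets, and 5 lists passed camera (smallest adjusted p = 0.989 with an estimated correlation).

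The fall of muscle genes was also seen against 6 weeks. In a comparison of PBS at 12 with 6 weeks, added after the data had been seen, 73 genes changed, 1 higher and 72 lower. Muscle genes fell in 18 of 20 (19 over the list alone, median −4.20, camera adjusted p = 2.8e-64, adjusted p = 0.0015 with an estimated correlation). Among them were Tnnc2 −4.53 (0.54, 2.9e-04), Ttn −5.30 (0.65, 2.9e-04) and Neb −5.42 (0.75, 4.7e-04). The mean of the muscle list changed by −4.006 (95% interval −5.173 to −2.838). Without PBS at 6 weeks replicate 1 or 3 the count was 27 or 38, and without PBS at 12 weeks replicate 1 or 3 it was 30 or 40. Every comparison with PBS at 12 weeks below therefore carries muscle genes on its higher side.

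After 6 weeks of jak1i the genes of killer lymphocytes had fallen against PBS at 6 weeks (n = 3 each). Granzyme genes Gzma −4.70 (0.71, 0.00333) and Gzmb −4.68 (0.73, 0.00409), the chemokine gene Ccl5 −3.59 (0.47, 0.00193), the pore gene Prf1 −1.11 (0.21, 0.0103) and Cd8a −1.43 (0.29, 0.0177) fell. Interferon-induced genes fell as well, with Cxcl11 −3.98 (0.97, 0.042), Oasl2 −3.14 (0.60, 0.0112), Mx1 −2.59 (0.56, 0.0238) and the peptide transporter gene Tap1 −1.33 (0.27, 0.0163), whereas Cxcl9 −3.99 (1.07, 0.065), Cxcl10 −3.89 (1.01, 0.0545) and Ifng −2.31 (0.60, 0.0559) did not pass. The keratin gene Krt6b −5.53 (1.29, 0.0344), which marks stressed epidermis, and the cystatin gene Stfa3 −4.74 (0.79, 0.00467) were the largest falls. The largest rises were Scgb1a1 3.19 (0.65, 0.0163), Dbp 3.09 (0.78, 0.0491) and Stmn2 1.40 (0.30, 0.0227). The feedback genes Bcl3 −1.94 (0.35, 0.00925) and Cish −0.90 (0.21, 0.0331) fell as members of a list of STAT targets. In that list 3 genes fell over all genes and 7 over the list alone (median −0.57, camera adjusted p = 4.2e-07, adjusted p = 0.0181 with an estimated correlation). In the cytotoxic list 13 of 21 members fell (18 over the list alone, median −1.39, camera adjusted p = 1.6e-25, adjusted p = 0.0181 with an estimated correlation). The interferon-γ list had 10 of 25 falls (24 over the list alone, median −1.79, camera adjusted p = 4.9e-26, but adjusted p = 0.0816 with an estimated correlation). The type I interferon list had 11 of 18 (15 over the list alone, median −1.48) and the T cell list 7 of 19 (11 over the list alone), each with an adjusted p = 0.0816 with an estimated correlation. Hair shaft genes did not pass, with a median of −1.65 and Krtap15 −1.59 (1.73, 0.667), nor did fat cell genes over all genes (median 1.5, 10 of 15 higher over the list alone, Adipoq 2.76 (0.79, 0.0854)). In total 248 of 18193 genes changed, 26 higher and 222 lower, of which 5 and 121 at least 2-fold. Groups did not overlap in 247 of them, against 18.5% of all genes and 10% by chance. The count rests on single arrays and on the pooled variance. It was 20 in a fit to the compared arrays, 13, 395 and 107 without jak1i at 6 weeks replicate 1, 2 and 3, and 559, 31 and 23 without PBS at 6 weeks replicate 1, 2 and 3.

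After 6 weeks of jak3i, lymphocyte and interferon genes had fallen against PBS at 6 weeks (n = 3 each). The chemokine genes for CXCR3, Cxcl11 −5.25 (0.97, 0.00673), Cxcl9 −5.22 (1.07, 0.0124) and Cxcl10 −4.95 (1.01, 0.0117), fell. The lymphocyte genes Gzma −4.98 (0.71, 0.00264), Gzmb −4.82 (0.73, 0.00352), Ccl5 −3.83 (0.47, 6.4e-04), Ifng −2.37 (0.60, 0.0431), Cd8a −1.37 (0.29, 0.0167) and Prf1 −0.88 (0.21, 0.0305) fell too, while Klrk1 −1.18 (0.32, 0.0543) did not pass. Further falls were Ubd −5.06 (1.06, 0.0138), Tap1 −1.74 (0.27, 0.00382), Mx1 −2.81 (0.56, 0.00997), Bcl3 −1.58 (0.35, 0.0222) and Cish −0.87 (0.21, 0.0317). Krt6b −5.97 (1.29, 0.0176) was the largest fall, and the fat cell gene Adipoq 3.29 (0.79, 0.0325) the largest rise, ahead of Cyp2f2 3.03 and Rbp4 3.02. Of the interferon-γ list 18 of 25 genes fell (23 over the list alone, median −2.03, camera adjusted p = 2.5e-29, adjusted p = 0.0533 with an estimated correlation). Of the cytotoxic list 15 of 21 fell (18 over the list alone, median −1.53, camera adjusted p = 5.7e-25, adjusted p = 0.0400 with an estimated correlation). Type I interferon genes fell in 11 of 18 (15 over the list alone, median −1.73) and MHC class I genes in 7 of 11 (11 over the list alone, median −1.32), each with an adjusted p = 0.0533 with an estimated correlation. Fat cell genes rose in 5 of 15, among them Retn 2.66 and Cidec 2.99 (13 over the list alone, median 2.02, adjusted p = 0.116 with an estimated correlation). The hair shaft list had 0 calls at a median of −2.23, and Krtap15 −2.75 (1.73, 0.445). In total 353 genes changed, 81 higher and 272 lower, of which 41 and 165 at least 2-fold, 345 of them without overlap of the groups (15.6% of all genes, 10% by chance). Centring gave 407, 170 higher and 237 lower, and the compared arrays alone gave 39. The count was 1142, 202 and 222 without jak3i at 6 weeks replicate 1, 2 and 3, and 825, 69 and 76 without PBS at 6 weeks replicate 1, 2 and 3.

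At 12 weeks of jak1i against PBS at 12 weeks (n = 3 each) the cytotoxic genes Gzma −4.57 (0.71, 6.1e-04), Gzmb −4.41 (0.73, 0.00107), Ccl5 −3.59 (0.47, 1.5e-04) and Ifng −3.10 (0.60, 0.00342) fell. So did the T cell genes Cd8a −1.86 (0.29, 7.2e-04), Cd3d −1.23 (0.21, 0.00116) and Cxcr6 −2.19 (0.39, 0.00174) and the NK receptor genes Klrc1 −2.85 (0.44, 5.2e-04) and Klrk1 −1.70 (0.32, 0.00277). Prf1 −0.48 (0.21, 0.123) did not pass. Chemokine genes Cxcl9 −4.03 (1.07, 0.0177), Cxcl10 −3.92 (1.01, 0.015) and Cxcl11 −4.54 (0.97, 0.00562) and the ubiquitin-like gene Ubd −4.20 (1.06, 0.0138) fell, and so did Oasl2 −3.18 (0.60, 0.00283) and Mx1 −2.80 (0.56, 0.00392), which answer type I interferon. Stressed keratinocytes lost Krt6b −5.33 (1.29, 0.0116), Sprr1b −5.03 (1.41, 0.022) and Stfa3 −4.13 (0.79, 0.003), and the collagenase gene Mmp13 −5.02 (1.05, 0.00504) fell among the 10 largest, with Gbp8 −4.45 (1.03, 0.0091) and Aldh1a3 −4.19 (0.84, 0.00382). The largest rises were muscle genes, Neb 6.09 (0.75, 9.1e-05), Myot 5.88 (0.78, 1.5e-04), Ttn 5.84 (0.65, 5.4e-05), Smpx 5.61, Klhl41 5.50, Tnnt3 5.50, Myh4 5.45, Myh2 5.42, Mybpc2 5.37 and Apobec2 5.25, which are low in PBS at 12 weeks. Beside them rose the growth factor gene Fgf18 3.19 (0.69, 0.00593) and Krt15 1.78 (0.37, 0.00472) of the follicle bulge, the lipid gene Scd3 3.24 (0.97, 0.0305) and Far2 2.69 (0.57, 0.00555) of the sebaceous gland, and Scgb1a1 3.75, Slc26a7 4.48 and Cd163 2.20. Krtap15 −5.23 (1.73, 0.0484) and Krtap26-1 −4.21 (1.40, 0.049) fell among hair shaft genes, whereas Krt31 −3.59 (1.45, 0.0995) and the follicle regulators Foxn1 −1.32 (0.62, 0.158) and Hoxc13 −0.93 did not pass.

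By lists, jak1i against PBS at 12 weeks lowered 17 of 21 cytotoxic genes (20 over the list alone, median −1.70, camera adjusted p = 2.0e-16, adjusted p = 0.108 with an estimated correlation). It lowered 20 of 25 interferon-γ genes (25 over the list alone, median −1.75, adjusted p = 0.238) and 16 of 18 type I interferon genes (18, median −1.76, adjusted p = 0.156), each p with an estimated correlation. It lowered 7 of 11 MHC class I genes such as Tap1 −1.27 and Psmb9 −1.44 (10, median −1.04, adjusted p = 0.251 with an estimated correlation). MHC class II genes fell in 6 of 8 (7, among them H2-Ab1 −0.91 (0.24, 0.0185) and Ctss −1.68, adjusted p = 0.251 with an estimated correlation) and T cell genes in 11 of 19 (14, median −0.66, adjusted p = 0.156 with an estimated correlation). Stressed keratinocyte genes fell in 8 of 15 (14, median −3.34, adjusted p = 0.215 with an estimated correlation). Neutrophil genes fell in 5 of 12, among them Lcn2 −3.48 and Fpr2 −2.45 (7, adjusted p = 0.238 with an estimated correlation). Of macrophage genes Fcgr1 −2.95, Msr1 −2.02 and Itgam −1.43 fell and Cd163 rose (adjusted p = 0.489 with an estimated correlation). Muscle genes rose in 19 of 20 (19, median 4.68, camera adjusted p = 8.7e-29, adjusted p = 0.0863 with an estimated correlation). Bulge genes rose in 5 of 10 (7, median 1.04, adjusted p = 0.156 with an estimated correlation) and sebaceous genes in 6 of 15, such as Fa2h 2.64 (10, median 0.98, adjusted p = 0.251 with an estimated correlation). Fat cell genes rose in 2 of 15, Slc2a4 1.42 and Car3 0.92, the latter picked after its value had been seen (2, median 1.12, adjusted p = 0.448 with an estimated correlation), while Adipoq 1.82 (0.79, 0.125) did not pass. Hair shaft genes fell in 2 of 45 over all genes and 30 over the list alone (median −3.93, camera adjusted p = 2.4e-10, adjusted p = 0.475 with an estimated correlation). Inner root sheath genes fell in 0 of 14 and 3 (median −3.38) and cell cycle genes in 0 and 0 (median −0.69, camera adjusted p = 1.2e-04), each with an adjusted p = 0.489 with an estimated correlation. The melanocyte list did not pass, and its median of −0.28 and mean of −0.20 differ in sign from the camera direction (adjusted p = 0.936). Camera called 19 of the 35 lists and 0 with an estimated correlation.

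In total jak1i at 12 weeks against PBS at 12 weeks changed 2431 of 18193 genes in limma, 1246 higher and 1185 lower, of which 519 and 411 at least 2-fold, and 2396 had no overlap between the groups (36.2% of all genes, 10% by chance). The count was 1222, 1400 and 929 without jak1i at 12 weeks replicate 1, 2 and 3, and 1335 and 597 without PBS at 12 weeks replicate 1 and 3. With the PBS arrays at 6 weeks as the control 15 genes passed, with 6 of 21 cytotoxic, 0 of 25 interferon-γ, 1 of 18 type I interferon, 0 of 19 T cell and 0 of 11 MHC class I genes lower. The medians of these lists were then −1.29, −1.63, −1.60, −0.41 and −0.98. Of the rises above, 0 bulge, sebaceous and fat cell genes passed, at medians of 0.87, 0.66 and 1.66. With the muscle list mean as covariate 0 genes passed, at medians of −0.84 for cytotoxic and −1.75 for interferon-γ genes. The hair shaft list mean left 393, in which 11 cytotoxic, 11 type I interferon and 1 interferon-γ gene fell, at medians of −1.45, −1.38 and −1.51. Stressed keratinocyte genes then fell in 2 of 15, and 0 bulge, sebaceous and fat cell genes rose (medians 0.76, 0.425 and 0.59).

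At 12 weeks of jak3i against PBS at 12 weeks (n = 3 each) the lymphocyte genes Gzma −5.47 (0.71, 9.0e-05), Gzmb −4.02 (0.73, 0.00193), Ccl5 −3.80 (0.47, 6.1e-05), Ifng −3.07 (0.60, 0.00318), Cd8a −1.80 (0.29, 7.3e-04), Prf1 −1.43 (0.21, 2.4e-04), Klrc1 −2.99, Klrk1 −1.78, Fasl −2.20 and Il2rb −1.81 fell. Of the interferon-γ response Cxcl9 −4.27 (1.07, 0.0121), Cxcl10 −3.85, Cxcl11 −4.62, Ubd −4.51 and Tap1 −1.21 fell. Of the 10 largest falls 9 were hair shaft genes, which encode the proteins that fill the hair fibre, with Krtap14 −5.95 (1.81, 0.0291), Krtap15 −5.82 (1.73, 0.0264), Krtap7-1 −5.76 (1.81, 0.0333), Krt33a −5.64 (1.79, 0.0348), Krt86 −5.57 (1.73, 0.0319), Krtap4-16 −5.55, Krtap11-1 −5.54, Krtap9-3 −5.49 and Krtap13-1 −5.45. The inner root sheath genes Krt28 −5.08 (1.67, 0.04) and Krt27 −4.83 (1.48, 0.0298) and the mitosis genes Plk1 −1.27 (0.35, 0.0192), Cdk1 −1.27 (0.41, 0.0377) and Ube2c −1.35 fell too. Krt31 −3.80 (1.45, 0.0716), Mx1 −1.43 (0.56, 0.0795) and Ifit1 −1.56 (0.55, 0.0544) did not pass, whereas Oasl2 −1.74 (0.60, 0.0475) did. Endothelial genes rose, Vwf 1.94 (0.40, 0.00408), Ptprb 1.67, Emcn 1.58, Tek 1.51 and Cdh5 1.31, and so did the myelin gene Mbp 2.24 (0.51, 0.00745), Krt2 2.76 (0.81, 0.0249) of the upper epidermis, Scd3 3.11, Far2 2.55 and Fgf18 2.85. The 10 largest rises were muscle genes, among them Neb 6.36 (0.75, 4.7e-05), Myot 6.05, Myh2 5.96, Ttn 5.94, Klhl41 5.81 and Ckmt2 5.58.

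By lists, jak3i against PBS at 12 weeks lowered 19 of 21 cytotoxic genes (20 over the list alone, median −1.99, camera adjusted p = 4.0e-20, adjusted p = 0.0572 with an estimated correlation). It lowered 16 of 25 interferon-γ genes (23, median −1.45, adjusted p = 0.347) and 8 of 18 type I interferon genes (10, median −0.98, adjusted p = 0.375), each p with an estimated correlation. T cell genes fell in 13 of 19, Cd2 −1.82 and Cd3d −1.49 among them (16, adjusted p = 0.224 with an estimated correlation). MHC class I genes fell in 8 of 11 (9) and MHC class II genes in 5 of 8 (7), each with an adjusted p = 0.347 with an estimated correlation. The plasma cell gene Jchain −3.15 fell among 4 of 13 B and plasma cell genes (4, adjusted p = 0.375 with an estimated correlation). Hair shaft genes fell in 16 of 45 (40 over the list alone, median −4.45, camera adjusted p = 3.5e-12), inner root sheath genes in 8 of 14 (11, median −4.47) and cell cycle genes in 7 of 24 (16, median −0.96). Each of these 3 lists had an adjusted p = 0.375 with an estimated correlation. Hair matrix genes fell in 2 of 19 (0, median −0.89, adjusted p = 0.655 with an estimated correlation). Stressed keratinocytes lost 2 of 15 genes, Krt6a −1.72 and Krt17 −1.33, picked after their values had been seen (3, adjusted p = 0.398 with an estimated correlation), while Krt6b −1.82 (1.29, 0.338) did not pass. Muscle genes rose in 19 of 20 (20, median 4.76, camera adjusted p = 8.6e-27, adjusted p = 0.0572 with an estimated correlation). Endothelial genes rose in 12 of 16 (13, median 1.28, camera adjusted p = 9.8e-07), sebaceous genes in 7 of 15 (9), bulge genes in 5 of 10 (5) and Schwann cell genes in 2 (5). Each of these 4 lists had an adjusted p = 0.347 with an estimated correlation. Fat cell genes rose in 4 of 15, with Thrsp 3.14 but not Adipoq 1.69 (0.79, 0.137) (5, median 1.07, adjusted p = 0.375 with an estimated correlation). The macrophage list had a median of −0.02 but a mean of 0.05 (adjusted p = 0.966). The dermal papilla list turned from a median of 0.10 to −0.04 after centring. Camera called 23 of 35 lists and 0 with an estimated correlation.

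In total jak3i at 12 weeks against PBS at 12 weeks changed 3148 genes in limma, 1823 higher and 1325 lower, of which 737 and 300 at least 2-fold, and 3035 had no overlap between the groups (38.3% of all genes, 10% by chance). Values are on the deposited scale and lie lower by 0.14 relative to the array medians. On the deposited scale the median change over all genes was −0.035. After centring 4268 genes passed, 1252 higher and 3016 lower, so the share of higher genes went from 57.9% to 29.3%, while 26 hair shaft, 21 interferon-γ and 14 cell cycle genes fell. The count was 854 and 1637 without jak3i at 12 weeks replicate 1 and 2, and 1198 and 951 without PBS at 12 weeks replicate 1 and 3. With PBS at 6 weeks as the control 419 genes passed, with 15 cytotoxic, 6 interferon-γ, 6 T cell, 1 type I interferon and 4 MHC class I genes lower, 9 endothelial genes higher and 0 hair shaft genes (median −4.28). With the muscle list mean as covariate 0 genes passed, at medians of −1.45 for cytotoxic, −1.49 for interferon-γ and 0.03 for endothelial genes. The hair shaft list mean left 198, with 12 cytotoxic and 0 interferon-γ genes lower (medians −1.52 and −1.17) and 1 of 16 endothelial genes higher (median 0.69). In both of these settings, and with PBS at 6 weeks, 0 sebaceous, bulge and fat cell genes rose.

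Either inhibitor at 12 weeks (n = 6) was set against PBS at 12 weeks (n = 3). The fall of Gzma −5.02 (0.62, 1.7e-05), Gzmb −4.22 (0.62, 1.3e-04), Ifng −3.09 (0.51, 4.0e-04), Cd8a −1.83 (0.25, 5.0e-05) and Cxcl9 −4.15 (0.91, 0.00341) passed with smaller errors than in each arm. The genes Socs1 −0.83 (0.27, 0.0305), Krt31 −3.69 (1.23, 0.0332), Mx1 −2.11 (0.54, 0.00791) and Krt6b −3.58 (1.26, 0.0426) passed too. The largest falls were Krtap14 −5.61 (1.54, 0.0123), Krtap15 −5.52 (1.47, 0.0104) and Krtap4-16 −5.18, and the largest rises Neb 6.22 (0.64, 2.4e-06), Myot 5.96 and Ttn 5.89 (0.55, 1.4e-06). In total 4293 genes changed, 2270 higher and 2023 lower, of which 722 and 454 at least 2-fold. After centring there were 4495, 1695 higher and 2800 lower, so the share of higher genes went from 52.9% to 37.7%. Without PBS at 12 weeks replicate 1 or 3 the count was 2261 or 1470, and with PBS at 6 weeks as the control it was 816. Camera called 19 lists, and the smallest adjusted p with an estimated correlation was 0.0652.

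Against its own arm at 0 weeks, jak1i at 12 weeks (n = 3 each) lowered Gzmb −5.24 (0.73, 7.5e-04), Gzma −4.92 (0.71, 7.5e-04), Ccl5 −3.95 (0.47, 3.9e-04), Ifng −2.91 (0.60, 0.00457), Cd8a −2.21 (0.29, 6.3e-04), Klrc1 −3.29, Fasl −2.57 and Prf1 −0.76 (0.21, 0.0179). The chemokine genes Cxcl11 −4.78, Cxcl9 −4.19 (1.07, 0.0124) and Cxcl10 −3.77 fell with Ubd −4.43, and the type I interferon genes Oasl2 −3.36 (0.60, 0.00231), Mx1 −3.31 (0.56, 0.00191) and Ifit1 −3.09 with Rtp4 −2.60. Krt6b −5.0 (1.29, 0.0132), Aldh1a3 −4.95 (0.84, 0.00188), Mmp13 −4.74 (1.05, 0.00603) and Sprr1b −4.52 (1.41, 0.032) fell as well. The largest rises were the anion transporter gene Slc26a7 5.14 (1.11, 0.00536), Cyp2e1 4.86 (0.95, 0.00358), the lipid gene Thrsp 4.76 (1.06, 0.00615), Scgb1a1 4.09 (0.65, 0.00136), Ces1d 4.03, Adipoq 3.66 (0.79, 0.00536), Ifitm6 3.55, Cdo1 3.54, Rbp4 3.45 and Aadacl2fm1 3.45, several of which are made in fat cells. Mast cell proteases rose, Cpa3 3.06 (0.81, 0.0147), Cma1 2.58 and Mcpt4 2.46, and so did Krt15 1.85, Fgf18 3.13, Fa2h 2.68, Emcn 1.70 and Tek 1.78, whereas Flt1 −1.83 fell. Hair shaft genes did not pass over all genes, with Krtap19-2 −5.35 (2.05, 0.0755) and Krtap15 −4.94 (1.73, 0.0539).

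By lists, jak1i at 12 against 0 weeks lowered 17 of 21 cytotoxic genes (17 over the list alone, median −1.5, camera adjusted p = 2.3e-15, adjusted p = 0.254 with an estimated correlation). Interferon-γ genes fell in 20 of 25 (23, median −1.65) and type I interferon genes in 15 of 18 (17, median −1.92). T cell genes fell in 12 of 19 (14), MHC class I genes in 8 of 11 (11) and stressed keratinocyte genes in 9 of 15 (11, median −2.66). Each of these 5 lists had an adjusted p = 0.290 with an estimated correlation. Of epidermal differentiation genes 4 fell, Casp14 −1.68 and Flg −1.06 among them (5, adjusted p = 0.543 with an estimated correlation). Hair shaft genes fell in 0 of 45 over all genes and 37 over the list alone (median −4.25, camera adjusted p = 1.5e-10, adjusted p = 0.50 with an estimated correlation). Fat cell genes rose in 10 of 15, Retn 3.02, Pck1 3.00, Cidec 2.88 and Lep 2.09 among them (14, median 1.88, camera adjusted p = 5.8e-08, adjusted p = 0.305 with an estimated correlation). Sebaceous genes rose in 7 of 15 (10, adjusted p = 0.305) and bulge genes in 5 of 10 (6, adjusted p = 0.290), each p with an estimated correlation. Mast cell genes rose in 3 (5) and endothelial genes in 4 of 16 (8), each with an adjusted p = 0.50 with an estimated correlation. Dermal papilla genes rose in 3, Rspo3 1.74 and Sox2 1.2 among them, and the list did not pass (adjusted p = 0.0653). Of the muscle genes Myh2 2.91 (0.69, 0.00844) rose (1 of 20, also over the list alone, median 0.85, adjusted p = 0.543 with an estimated correlation). The dendritic cell list had a median of 0.00, and −0.06 after centring. Camera called 21 lists and 0 with an estimated correlation. In total 2958 genes changed in jak1i at 12 weeks vs 0 weeks, 1775 higher and 1183 lower, of which 578 and 386 at least 2-fold, and 2918 had no overlap (40.1% of all genes, 10% by chance). The count was 1411 without jak1i at 0 weeks replicate 1, and 1168 and 1711 without jak1i at 12 weeks replicate 1 and 3. With the hair shaft mean as covariate 535 genes passed, 10 cytotoxic and 6 interferon-γ genes among the falls (medians −1.25 and −1.58). Of the other lists, 1 bulge gene rose, 1 endothelial gene fell (median 0.37), and 0 fat cell (1.39), sebaceous (0.42) and stressed keratinocyte genes (−2.0) passed. With the muscle mean 1434 genes passed, 14 cytotoxic and 17 interferon-γ genes lower and 3 fat cell, 3 sebaceous and 1 endothelial gene higher.

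In the jak3i arm, 12 against 0 weeks (n = 3 each), the 10 largest falls were hair shaft genes, with Krtap16-3 −6.22 (1.90, 0.0422), Krtap15 −6.22 (1.73, 0.0339), Krtap19-3 −6.13 (1.91, 0.0446), Krtap14 −6.08 (1.81, 0.0397), Krtap9-3 −6.06, Krtap7-1 −6.06, Krt33a −6.01, Krtap11-1 −5.95, Krtap4-16 −5.93 and Krtap19-5 −5.91. Krt28 −5.38 (1.67, 0.0444), Krt27 −4.91, S100a3 −4.93, Vsig8 −4.60 and Plk1 −1.12 (0.35, 0.0471) fell too, but Krt31 −4.21 (1.45, 0.0614) and Hoxc13 −1.95 did not pass. Of the immune genes Gzma −4.81 (0.71, 0.00459), Gzmb −4.03 (0.73, 0.0141), Ccl5 −3.27 (0.47, 0.00444), Ifng −2.73 (0.60, 0.0208), Cd8a −1.15 (0.29, 0.0281) and Prf1 −1.28 (0.21, 0.00678) fell. So did Cxcl9 −4.34 (1.07, 0.0252), Cxcl11 −4.56, Ubd −4.37 and Tap1 −1.18, whereas Fasl −1.11 (0.37, 0.0572), Mx1 −1.43 (0.56, 0.0897) and Oasl2 −1.73 (0.60, 0.0608) did not pass. Rises were led by Slc26a7 3.73 (1.11, 0.0393), Thrsp 3.57 (1.06, 0.0395), Scgb1a1 3.37 (0.65, 0.0176), Cyp2e1 3.16, Ces1f 2.92, Krt2 2.88 (0.81, 0.0344), Aplnr 2.86 (0.47, 0.00678), Cyp2f2 2.68, Aadacl2fm1 2.59 and Gucy1a1 2.58. The endothelial genes Emcn 2.04, Vwf 1.77, Cdh5 1.75 and Ptprb 1.72, the Schwann cell gene Mbp 1.90 and the mast cell gene Tpsb2 1.47 (0.45, 0.0413) rose, and Adipoq 1.98 (0.79, 0.0951) did not pass.

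By lists, jak3i at 12 against 0 weeks lowered 23 of 45 hair shaft genes (44 over the list alone, median −5.23, camera adjusted p = 2.7e-18), 7 of 14 inner root sheath genes (11, median −4.72), 3 of 19 hair matrix genes (4, median −1.34) and 2 of 24 cell cycle genes (15, median −0.95), each with an adjusted p = 0.406 with an estimated correlation. It lowered 15 of 21 cytotoxic genes (18, median −1.35, camera adjusted p = 7.6e-16, adjusted p = 0.244 with an estimated correlation). It lowered 17 of 25 interferon-γ genes (22, median −1.45), 4 of 18 type I interferon genes (9, median −0.88), 7 of 11 MHC class I genes (8, median −1.0) and 3 of 19 T cell genes (9, median −0.44), each with an adjusted p = 0.406 with an estimated correlation. Endothelial genes rose in 10 of 16 (13, median 1.36, camera adjusted p = 3.1e-07), Schwann cell genes in 3 (4, median 0.67), sebaceous genes in 2 of 15 (6, median 0.78) and mast cell genes in 1 (6, median 1.30). Fat cell genes rose in 2 of 15, Acaca 1.17, picked after its value had been seen, and Thrsp (9, median 1.26). Each of these 5 lists had an adjusted p = 0.406 with an estimated correlation. Of 10 bulge genes 2 rose without a call for the list (adjusted p = 0.104), and muscle genes had 0 calls (median 0.68, adjusted p = 0.0944). Medians and means differed in sign for JAK and STAT genes (0.20 and −0.05), dermal papilla genes (−0.04 and 0.07) and macrophage genes (0.04 and −0.02). Camera called 20 lists and 0 with an estimated correlation. In total 1867 genes changed in jak3i at 12 weeks vs 0 weeks, 1348 higher and 519 lower, of which 384 and 164 at least 2-fold, and 1843 had no overlap (38.9% of all genes, 10% by chance). Values lie lower by 0.17 relative to the array medians, and after centring 3040 genes passed, 720 higher and 2320 lower (23.7% higher against 72.2%), with 38 hair shaft, 21 interferon-γ and 18 cytotoxic genes lower. The medians of 5 lists turned sign by centring, macrophage from 0.04 to −0.13, dendritic cell from 0.04 to −0.13, epidermal differentiation from 0.08 to −0.09, immediate early from 0.03 to −0.13 and ribosomal from 0.01 to −0.15. The count rests on single arrays, with 333 and 1 without jak3i at 0 weeks replicate 1 and 2, and 14 and 21 without jak3i at 12 weeks replicate 1 and 2. With the hair shaft mean as covariate 0 genes passed, at medians of −1.10 for cytotoxic, −1.39 for interferon-γ, 0.52 for fat cell and 0.78 for endothelial genes, and 271 with the muscle mean.

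Many of the calls were shared by the 2 arms. Of the genes called at 12 against 0 weeks, 710 were higher and 247 lower in both arms and 0 had opposite signs, against 131.5 and 33.7 if calls were independent, and 351 of these 957 changed at least 2-fold in both. Leaving out arrays, a check added after the data had been seen, gave 183 and 0 shared genes without jak3i at 0 weeks replicate 1 and 2, and 9 and 13 without jak3i at 12 weeks replicate 1 and 2. It was 457 and 592 without jak1i at 0 weeks replicate 1 and 3, and 395 and 588 without jak1i at 12 weeks replicate 1 and 3. None had opposite signs. Both arms also shifted in the hair shaft list mean (−3.893 and −4.859), so independence is no measure of no change here. With that mean as covariate 0 shared genes remained, since jak3i had 0 calls, and with the muscle mean 117. The first principal component of the 2000 most variable genes held 57.05% of their variance and correlated with the hair shaft mean at 0.91 over the 31 arrays. Gzma, Gzmb, Cxcl9, Ubd and Tap1 are among the shared falls and Scgb1a1, Slc26a7, Thrsp, Emcn and Mbp among the shared rises. Against PBS at 12 weeks 956 genes were shared higher and 681 lower (124.9 and 86.3 if independent), but these 2 comparisons use the same PBS arrays. Simulated unchanged groups sharing controls gave 0 and 0 shared genes in 20 runs, and a correlation across genes of 0.477 against 0.923 here. They held no shift common to the PBS arrays, like that of muscle genes, so the effect of sharing them is left open. The scatter below places all 45 hair shaft, 21 cytotoxic and 25 interferon-γ genes below 0 on both axes and all 15 fat cell genes above, whether past the threshold or not. In jak1i and jak3i 0 and 23 hair shaft, 17 and 15 cytotoxic, 20 and 17 interferon-γ and 10 and 2 fat cell genes passed.

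**Figure D1:**
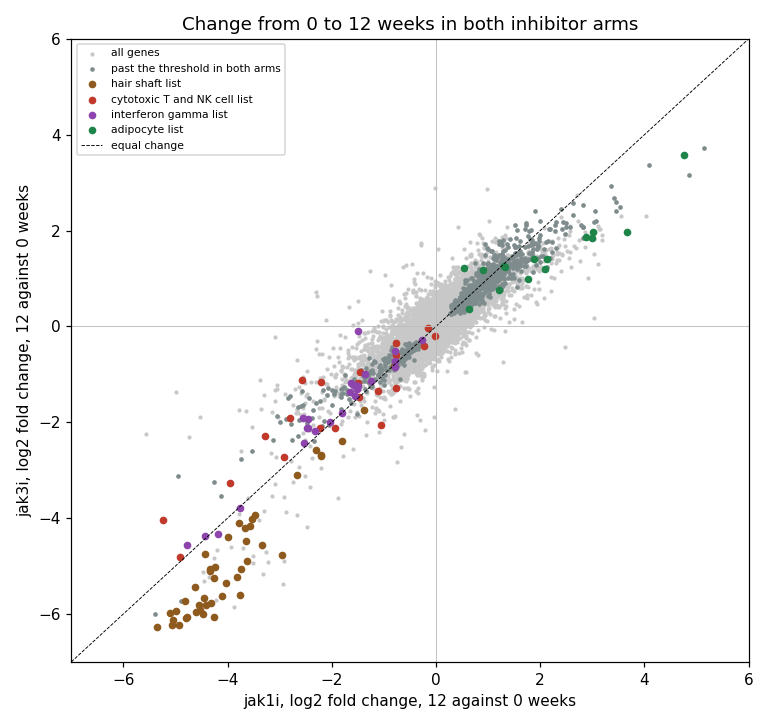
Log2 change from 0 to 12 weeks in the jak1i arm (horizontal) and the jak3i arm (vertical), a point per gene, with the 957 genes past the threshold in both arms darker, list genes coloured and the dashed line marking equal change. Hair shaft genes reach −6.28 in jak3i.

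Within 6 weeks of jak1i against its own start (n = 3 each), Krt6b −6.61 (1.29, 0.00388), Gzmb −5.64 (0.73, 2.0e-04) and Gzma −5.63 (0.71, 1.8e-04) were the largest falls and Cyp2e1 4.54, Thrsp 4.39 (1.06, 0.0123) and Ces1d 3.78 the largest rises. Prf1 −1.57 (0.21, 2.1e-04), Cd8a −2.12 (0.29, 3.2e-04), Mx1 −3.59 (0.56, 8.0e-04), Socs1 −1.03 (0.32, 0.04) and Cish −1.03 (0.21, 0.00451) fell, and Adipoq 3.52 (0.79, 0.0086) and the mast cell gene Cpa3 3.33 (0.81, 0.0129) rose. Of the lists 17 of 21 cytotoxic (17 over the list alone, adjusted p = 0.0622), 22 of 25 interferon-γ (25, adjusted p = 0.216) and 16 of 18 type I interferon genes (17, adjusted p = 0.121) fell, each p with an estimated correlation. Fat cell genes rose in 8 of 15 (12, median 1.96, adjusted p = 0.259) and mast cell genes in 5 (6, adjusted p = 0.318), each p with an estimated correlation. Hair shaft genes had 0 calls (median −1.98). In total 2250 genes changed, 1080 higher and 1170 lower, of which 407 and 362 at least 2-fold, with 2149 free of overlap (27.1% of all genes, 10% by chance). The count of jak1i at 6 weeks vs 0 weeks was 672 with the compared arrays, 926 and 1350 without jak1i at 0 weeks replicate 1 and 2, and 506 and 943 without jak1i at 6 weeks replicate 1 and 3.

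Within 6 weeks of jak3i (n = 3 each), Krt6b −6.92 (1.29, 0.00583), Cxcl11 −5.76 (0.97, 0.0032) and Cxcl9 −5.75 (1.07, 0.00583) fell most and Ces1f 3.48, Cyp2f2 3.02 and Scgb1a1 2.91 (0.65, 0.0184) rose most. Gzma −4.91 (0.71, 0.00144), Gzmb −4.97 (0.73, 0.00149), Mx1 −3.31 (0.56, 0.0032), Socs3 −1.19 (0.30, 0.0345) and the kinase gene Jak2 −0.63 (0.15, 0.026) fell, and Cd8a −1.05 (0.29, 0.0507) did not pass. The lists lost 12 of 21 cytotoxic (18 over the list alone), 20 of 25 interferon-γ (24), 15 of 18 type I interferon (18) and 4 of 15 stressed keratinocyte genes (14, median −3.48), each with an adjusted p = 0.0853 with an estimated correlation. Fat cell genes had 0 calls over all genes and 13 of 15 over the list alone (median 1.55, adjusted p = 0.291 with an estimated correlation), and hair shaft genes 0 (median −3.11). In total 573 genes changed, 200 higher and 373 lower, of which 80 and 230 at least 2-fold, with 560 free of overlap (19.6% of all genes, 10% by chance). Centring gave 710, 329 higher and 381 lower, the compared arrays 59 and the set without dim genes 895. The count of jak3i at 6 weeks vs 0 weeks was 211, 73 and 1020 without jak3i at 0 weeks replicate 1, 2 and 3, and 2463, 223 and 286 without jak3i at 6 weeks replicate 1, 2 and 3.

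At 24 weeks (n = 2 against n = 3 at 0 weeks) jak1i had lower Gzma −4.20 (0.80, 0.0316), Gzmb −3.38 (0.82, 0.047), Fasl −2.34 (0.42, 0.0316), Cd8a −1.85 (0.33, 0.0316), Ccl5 −2.24 (0.53, 0.0441) and Prf1 −1.02 (0.23, 0.0436). The genes Cxcl9 −2.68 (1.2, 0.208) and Mx1 −2.14 (0.63, 0.0683) did not pass. Rises were Scgb1a1 3.70 (0.73, 0.0316), Cd209e 3.67 (0.72, 0.0316), Ifitm6 3.55 (0.85, 0.0449), Mbp 2.37 (0.57, 0.0467) and Il34 1.34 (0.27, 0.0316). Of the cytotoxic list 7 of 21 genes fell (14 over the list alone, median −1.03, camera adjusted p = 9.5e-14, adjusted p = 0.364 with an estimated correlation), and 0 of the interferon-γ list (median −0.82) and of the hair shaft list (median −3.04). In total 216 genes changed, 188 higher and 28 lower, of which 82 and 12 at least 2-fold. Values lie lower by 0.12 relative to the array medians, and after centring 14 genes passed, 7 higher and 7 lower. The count of jak1i at 24 weeks vs 0 weeks was 50 with the compared arrays, 526 without dim genes, 25 with the mean of probe sets and 118 and 87 with a fixed and a random replicate block. It was 4, 6 and 81 without jak1i at 0 weeks replicate 1, 2 and 3, and 468 and 1 without jak1i at 24 weeks replicate 1 and 2.

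In jak3i at 24 weeks (n = 2 against n = 3) Gzmb −2.35 (0.82, 0.172), Gzma −2.0 (0.80, 0.218), Cd8a −0.13 (0.33, 0.876) and Cxcl9 −1.68 (1.2, 0.474) did not pass. The T cell gene Trat1 1.33 (0.22, 0.0372), the cytokine gene Il34 1.41 (0.27, 0.0392) and the MHC class II genes H2-Ob 1.47 (0.24, 0.0372) and H2-Oa 1.41 (0.27, 0.0392) rose, and Prrc2c −0.98, Rrp1b −0.75 and Pds5a −0.68 fell. T cell genes rose in 1 of 19, Trat1 (2 over the list alone, median 0.39, camera adjusted p = 0.0034, adjusted p = 0.599 with an estimated correlation). Cell cycle genes had 0 calls over all genes and 16 of 24 lower over the list alone (median −0.93, adjusted p = 0.599 with an estimated correlation). In total 20 genes changed, 17 higher and 3 lower (unadjusted p under 0.05 in 3122). Values lie lower by 0.15 relative to the array medians, and centring left 10, 2 higher and 8 lower. The count of jak3i at 24 weeks vs 0 weeks was 0 with the compared arrays, 0 with the mean of probe sets and 5 with a random replicate block. It was 2, 0 and 0 without jak3i at 0 weeks replicate 1, 2 and 3, and 310 and 1 without jak3i at 24 weeks replicate 1 and 2.

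**Figure D2:**
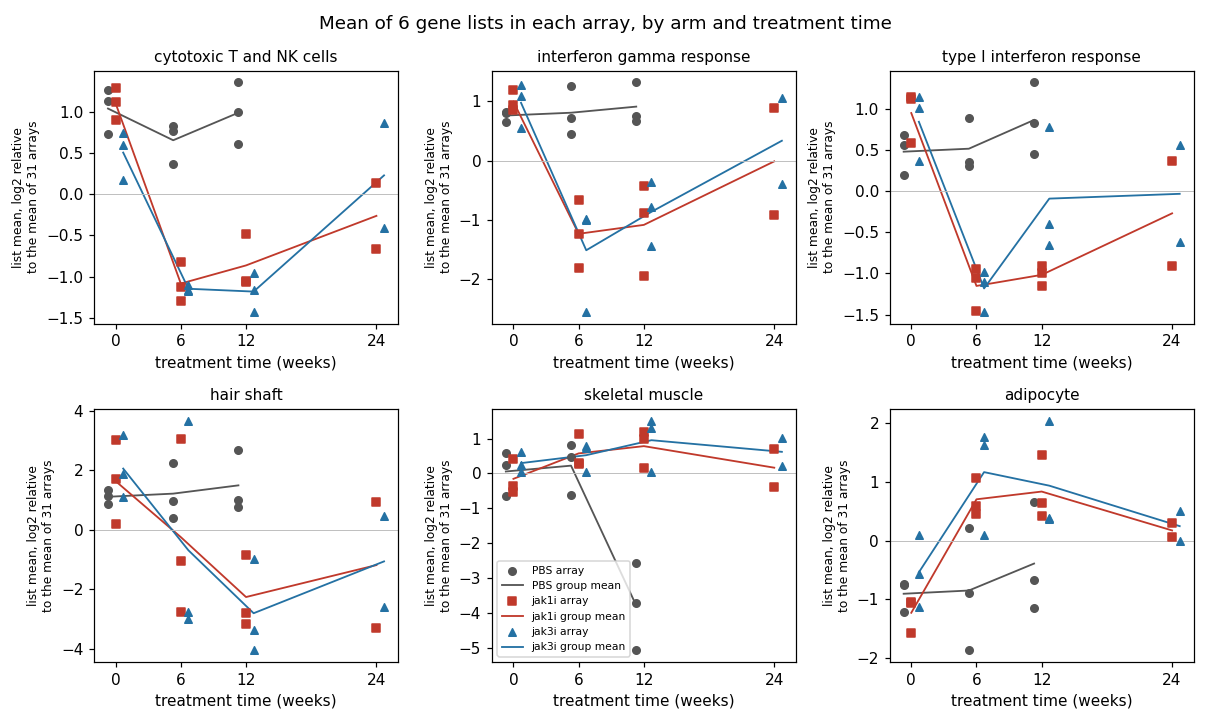
Mean log2 value of 6 gene lists relative to the mean of the 31 arrays, against treatment time in weeks, a point per array and a line per arm through the group means. The cytotoxic list falls from 1.105 to −0.864 in jak1i and from 0.506 to −1.182 in jak3i by 12 weeks, and the muscle list of PBS drops to −3.782 at 12 weeks.

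Change from 0 to 12 weeks was also compared between arms. Relative to the change under PBS, jak1i lowered Gzmb −4.80 (1.04, 0.014), Gzma −4.14 (1.01, 0.0199), Ifng −3.54 (0.85, 0.019), Cd8a −1.75 (0.42, 0.0182), Cxcl11 −4.79 (1.38, 0.0391), Krt6b −6.77 (1.83, 0.0309), Sprr1b −6.72 and Stfa3 −5.42, and Cxcl9 −4.25 (1.51, 0.0841) did not pass. It raised the sebaceous gene Fa2h 3.67 (0.87, 0.0176) and Ifitm6 3.72 (1.07, 0.0391). Muscle genes, which fell in PBS, lay higher (Myh2 7.68, Neb 6.43, Myot 6.42). Of the lists 15 of 18 type I interferon (17 over the list alone, adjusted p = 0.251), 12 of 21 cytotoxic (18, adjusted p = 0.216) and 8 of 25 interferon-γ genes (23, adjusted p = 0.328) fell, each p with an estimated correlation. Muscle genes lay higher in 18 of 20 (19, adjusted p = 0.169) and sebaceous genes in 4 of 15 (6, adjusted p = 0.328), each p with an estimated correlation. In total 1247 genes changed, 544 higher and 703 lower. The jak1i count was 2239 with the compared arrays. Without single arrays it was 777 and 482 (jak1i at 0 weeks replicate 1 and 3) and 747, 634 and 521 (jak1i at 12 weeks replicate 1 to 3). It was 346, 801 and 792 (PBS at 0 weeks replicate 1 to 3) and 646, 1916 and 276 (PBS at 12 weeks replicate 1 to 3).

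For jak3i the same contrast lowered Gzma −4.03 (1.01, 0.0316), Gzmb −3.60 (1.04, 0.0494), Ifng −3.37, Krtap31-1 −8.29 (2.24, 0.0424), Chil3 −5.38 and Gzmc −4.42. Muscle genes, which fell in PBS (Ttn −5.11), lay higher (Neb 6.51, Ttn 6.13, Myot 6.06). The lists lost 11 of 21 cytotoxic genes (17 over the list alone), 1 of 45 hair shaft genes (34, median −5.55), 4 of 24 cell cycle genes (22, median −1.5) and 1 of 25 interferon-γ genes (22), each with an adjusted p = 0.422 with an estimated correlation. Muscle genes lay higher in 18 of 20 (18, adjusted p = 0.234 with an estimated correlation). In total 827 genes changed, 471 higher and 356 lower. Values lie lower by 0.10 relative to the array medians, and centring gave 996, 365 higher and 631 lower. The jak3i count was 1894 with the compared arrays and 489 with a random replicate block. It was 212 and 143 (without jak3i at 0 weeks replicate 1 and 2), 0 and 460 (jak3i at 12 weeks replicate 1 and 2), 1, 255 and 325 (PBS at 0 weeks replicate 1 to 3) and 279 and 69 (PBS at 12 weeks replicate 1 and 3).

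Between the inhibitors no gene passed in limma at 6, 12 or 24 weeks (0, 0 and 0 genes, with 470, 1087 and 114 under an unadjusted p of 0.05). The smallest p at 12 weeks belonged to Pgap6 −1.14 (0.21, 0.277), Slfn4 −3.09 (0.61, 0.412), Stab1 −1.01 and the pore gene Prf1 0.94 (0.21, 0.554). At 6 weeks Kctd4 1.26, Lce1a2 0.92 and Lnx1 0.71 came first, at 24 weeks Krt2 3.68, Chil4 1.19 and Trat1 −0.90. The list mean of type I interferon genes at 12 weeks was lower in jak1i, with a difference of −0.926 (95% interval −1.709 to −0.143), with 3 of 18 members lower over the list alone and 0 over all genes (camera adjusted p = 2.3e-13, adjusted p = 0.371 with an estimated correlation). Without jak3i at 12 weeks replicate 3, left out after the data had been seen, the difference was −0.494 (−1.266 to 0.279), and without jak1i at 12 weeks replicate 3 it was −0.860 (−1.758 to 0.038). The means of 2 other lists were lower in jak1i by more, neutrophil genes by −1.263 (−2.207 to −0.320) and stressed keratinocyte genes by −1.533 (−3.050 to −0.017), with adjusted p = 0.327 and 0.594 with an estimated correlation. Without jak3i at 12 weeks replicate 3 they were −0.675 (−1.558 to 0.208) and −0.738 (−2.261 to 0.784). That array was the highest of the 6 in all 3 lists, at 0.773 for type I interferon, 1.651 for neutrophil and 1.638 for stressed keratinocyte genes. Endothelial genes were lower in jak1i as well, with a difference of −0.685 (interval −1.320 to −0.050, 4 of 16 over the list alone and 0 over all genes, adjusted p = 0.371 with an estimated correlation), but the interval took in 0 without jak1i at 12 weeks replicate 2 or 3 or jak3i replicate 2 or 3, with −0.555 (−1.272 to 0.162) nearest to 0. The cytotoxic list mean differed by 0.318 (−0.271 to 0.907), interferon-γ by −0.221 (−1.280 to 0.838), hair shaft by 0.544 (−2.829 to 3.917) and fat cell by −0.101 (−1.281 to 1.080). At 6 weeks the cytotoxic mean differed by 0.063 (−0.526 to 0.652) and interferon-γ by 0.278 (−0.781 to 1.337), and at 24 weeks by −0.492 (−1.213 to 0.230) and −0.348 (−1.645 to 0.949). Camera called 6, 10 and 7 lists at 6, 12 and 24 weeks, but 0, 0 and 0 with an estimated correlation (smallest adjusted p = 0.539, 0.327 and 0.539), and fry called 0 at each. Setting the changes from 0 weeks against each other, added after the data had been seen, gave 0, 0 and 0 genes, and for type I interferon at 12 weeks a difference of −1.032 (−2.139 to 0.075). A p that misses the threshold does not show that the compounds act alike. Single omissions gave 1 gene at 6 weeks without jak1i replicate 1 and 1 at 24 weeks without jak1i replicate 1 or 2.

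Transcripts of the kinases themselves moved little. Against PBS at 12 weeks Jak1 moved by 0.07 (0.15, 0.819) in jak1i and 0.10 (0.15, 0.66) in jak3i, Jak3 by −0.36 (0.14, 0.0914) and −0.06 (0.14, 0.808), and Tyk2 by −0.12 (0.11, 0.534) and −0.11 (0.11, 0.529), not past the threshold. Jak2 −0.46 (0.15, 0.0412) fell in jak1i from 0 to 12 weeks, and Jak2 −0.42 (0.15, 0.069) did not pass in jak3i. Among signal carriers Stat2 −1.68 (0.38, 0.0071) and Stat4 −0.84 fell in jak1i and Stat2 −1.55 (0.38, 0.0102) and Stat4 −0.90 in jak3i, and Stat5b 0.70 rose in jak3i. The cytokine gene Il15 −0.05 (0.24, 0.918) and 0.34 (0.24, 0.343) did not pass in either arm, nor did Socs1 −0.84 (0.32, 0.0849) and −0.83 (0.32, 0.0755).

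**Figure D3:**
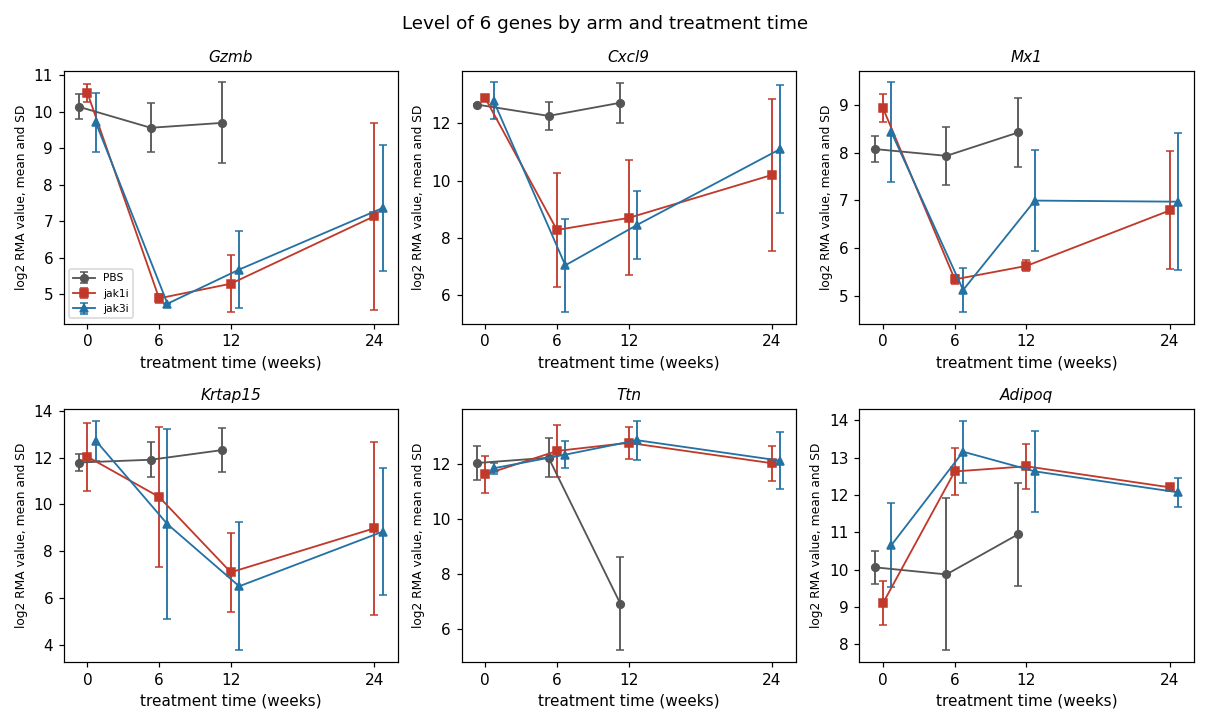
Group mean and standard deviation of the log2 RMA value of Gzmb, Cxcl9, Mx1, Krtap15, Ttn and Adipoq, by arm and week. Gzmb changes by −5.24 in jak1i and −4.03 in jak3i from 0 to 12 weeks, and Ttn by −5.11 in PBS.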

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

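Of the tests here, the comparisons of the effects at 12 and 6 weeks, the muscle member count, the ribosomal list, the splits of the hair shaft mean, the hair shaft and muscle covariates and the leukocyte lists were chosen only after the results had been seen. No group holds more than 3 arrays, so no array was tested for standing far from its group.

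The change from 0 to 12 weeks differed between jak1i and PBS in 1247 genes and between jak3i and PBS in 827, by a test of the difference itself. Killer cell genes such as Gzmb −4.80 and Gzma −4.14 in jak1i, and Gzma −4.03 and Gzmb −3.60 in jak3i, are among them, and so are the muscle genes Neb 6.43 (1.06, 0.00834) and Neb 6.51 (1.06, 0.0121). Relabelling the 4 groups gave as many genes in 1 of 100 splits for jak1i (highest other 835), a share under 0.05. For jak3i 3 of 100 splits gave as many (highest other 1464), also under 0.05. As PBS alone lost muscle genes, these shares cannot tell treatment from a sampling difference. Why other splits gave so many genes was not tested. Without single arrays the counts were 276 to 1916 for jak1i and 0 to 1182 for jak3i.

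The effect against PBS differed between 12 and 6 weeks in 2 genes for jak1i, Ttn 5.60 (0.91, 0.0328) and Tnnc2 4.63 (0.76, 0.0328), and in 38 for jak3i, all higher, led by Neb 6.11 (1.06, 0.0266), Ttn 5.83 (0.91, 0.0258) and Klhl41 5.82 (0.97, 0.0258). The muscle list rose in 1 of 20 members for jak1i (19 over the list alone, median 4.24, adjusted p = 0.0122 with an estimated correlation) and in 15 for jak3i (18 over the list alone, median 4.50, adjusted p = 0.0167 with an estimated correlation). Outside muscle, Hoxa7 1.98 (0.41, 0.044) and Pcdhgc4 1.34 (0.28, 0.044) passed for jak3i, both picked after their values had been seen. Without single arrays the jak1i count was 0 to 63 and the jak3i count 0 to 113, each 0 in 7 of 12 omissions.

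Among the 10092 probe sets without a single gene name, which no comparison by gene uses, 373 changed in jak1i against PBS at 12 weeks (205 higher, 168 lower), 343 in jak3i against PBS (201, 142), 635 in jak1i from 0 to 12 weeks (400, 235) and 251 in jak3i (185, 66). What these transcripts are was not analysed here.

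Skeletal muscle genes were low in all PBS arrays at 12 weeks. All 20 list members were lower in each of these 3 arrays than the median of the other 28 arrays, and 18 were below every other array, which is what less muscle in the sampled skin would give. From 0 to 12 weeks the ribosomal list mean rose by 0.123 (95% interval 0.048 to 0.199). The endothelial list moved by 0.210 (−0.424 to 0.845) and muscle by −3.838 (−5.006 to −2.671). RMA equalises arrays, so array-wide scaling could not show. The inhibitor arrays at 12 weeks were not low, with group means of 0.783 in jak1i and 0.953 in jak3i against −3.782 in PBS. RNA quality and why these 3 samples held less muscle were not tested.

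The hair shaft list mean was lower at 12 weeks under both inhibitors than under PBS, by −4.023, with −3.751 (95% interval −7.124 to −0.378) in jak1i and −4.295 (−7.668 to −0.923) in jak3i, but 2 and 16 of 45 genes passed, 0 and 0 with PBS at 6 weeks as the control, and the list lost its call with an estimated correlation. Of the 84 splits of the 9 arrays into 6 and 3, 1 gave a difference as large, the real one, but the list was picked after all 6 inhibitor arrays had been seen below the 3 PBS arrays, which fixes that result. An unequal follicle stage unrelated to the arm and a shift of the stage under treatment therefore cannot be told apart. Dilution by muscle RNA is argued against in jak3i, where the change from 0 weeks was −4.602 (95% interval −8.158 to −1.045) with the muscle mean as covariate and −4.859 without. In jak1i it was −3.526 (−7.200 to 0.147) with the covariate and −3.893 (−7.266 to −0.521) without, a smaller change with an interval that takes in 0.

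Cytotoxic and interferon-γ genes were lower at 12 than at 0 weeks under both inhibitors. With the muscle mean as covariate the change nearest to 0 was −1.621 (95% interval −2.235 to −1.007, cytotoxic list in jak3i), which argues against dilution by muscle RNA. With the hair shaft mean as covariate the cytotoxic change nearest to 0 was −1.248 (−1.873 to −0.623), against −1.688 without. For interferon-γ it was −1.346 (−2.589 to −0.102), against −1.837 without. Both arms also moved in that mean, so follicle stage and treatment cannot be told apart in either list. A loss of leukocytes of every kind is argued against, since dendritic cells moved by 0.044 (−0.326 to 0.414) and 0.115 (−0.255 to 0.486) and mast cells by 1.212 (0.085 to 2.339) and 1.296 (0.169 to 2.423), while the third list tested, macrophages, gave −0.129 (−1.032 to 0.774) in jak1i. Neutrophil genes fell in jak1i by −1.211 (−2.155 to −0.268) and moved in jak3i by −0.300 (−1.243 to 0.644), so a loss of several kinds is left open, as is a loss of killer lymphocytes alone or of their activation.

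Other splits of the arrays were counted for each comparison of 3 with 3 arrays, where 10 splits cannot give a share under 0.05. Against PBS, jak1i had 248 genes at 6 weeks with a highest other of 0, jak3i 353 with a highest other of 1050, and 2 of the 10 splits gave at least as many for jak3i, which points to a structure of those samples. At 12 weeks jak1i had 2431 (highest other 0) and jak3i 3148 (1), each reached by 1 of 10 splits. From 0 weeks, jak1i had 2250 (0) at 6 and 2958 (2) at 12 weeks, jak3i 573 (267) and 1867 (0), and PBS 1 (1, in 2 of 10) and 414 (1). With 0 genes, and so all 10 splits as large, stood jak1i and jak3i against PBS at 0 weeks (1 and 0) and jak1i against jak3i at 6 and 12 weeks (237 and 0), the 237 pointing to a structure of the arrays at 6 weeks. Either inhibitor against PBS at 12 weeks had 4293 genes with a highest other of 85 and 1 of 84 splits as large, a share under 0.05.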

How the results depend on the processing

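PBS at 6 weeks as the control and the hair shaft and skeletal muscle means as covariates were chosen only after the data had been seen, and so was leaving out arrays in the added contrasts, in the shared genes and in the list means of jak1i against jak3i. The cause of the differences below was not tested, except where fewer arrays or genes enter by construction, as in the fits to the compared arrays. Of the named genes, 1206 values by gene and setting kept direction and side of the threshold, 211 lost the call, 15 gained it and 8 turned. Detection calls were not used here, so signal over background was not judged gene by gene, and genes near the median of all values, 6.177, are limited by it.

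In fits to the compared arrays only, jak1i against PBS at 6 weeks gave 20 genes and jak3i 39, jak3i against PBS at 0 weeks 6, PBS at 6 weeks 0 and at 12 weeks 165 against its start, jak1i against its start 672 at 6 and 50 at 24 weeks, jak3i 59 and 0, and the changes relative to PBS 2239 for jak1i and 1894 for jak3i. With each array centred on its median, PBS at 12 against 0 weeks gave 242, jak1i at 24 against 0 weeks 14, jak3i at 12 against 0 weeks 3040 and at 24 weeks 10. Without dim genes (12825 kept, 5368 left out) jak1i at 24 against 0 weeks gave 526 and jak3i at 6 against 0 weeks 895. With the mean of probe sets PBS at 6 against 0 weeks gave 3, jak1i at 24 weeks 25 and jak3i at 24 weeks 0. The trended and robust variance moved no count by more than 1.5 times.

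The replicate block as a fixed term gave 118 genes for jak1i at 24 against 0 weeks. As a random block it gave 87 there, 5 for jak3i at 24 weeks and 489 for the jak3i change relative to PBS, with a consensus correlation of −0.0472. For jak3i against PBS at 12 weeks, where same-numbered arrays correlated, the fixed and random block gave 2828 and 3156 genes against 3148, and every array correlated best with its own number in 2 of 36 pairs of groups. The block moved no other count by more than 1.5 times.

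With PBS at 6 weeks as the control, jak1i at 12 weeks gave 15 genes, jak3i 419 and either inhibitor 816, and 43 named genes lost their call while 33 kept it. With the hair shaft mean as covariate jak1i and jak3i against PBS at 12 weeks gave 393 and 198 genes, and at 12 against 0 weeks 535 and 0. List medians that turned were inner root sheath in jak1i against PBS (0.019) and from 0 weeks (0.246), cell cycle in jak1i from 0 weeks (0.195), endothelial in jak1i against PBS (−0.025) and sebaceous in jak3i from 0 weeks (−0.004). With the muscle mean as covariate jak1i and jak3i against PBS gave 0 and 0 genes, since that mean separates PBS at 12 weeks from the inhibitor arrays, and from 0 weeks 1434 and 271. There the muscle genes Myot (−0.240), Tnnt3 (−0.528), Mybpc2 (−0.951) and Apobec2 (−0.111) turned in jak1i against PBS, and Myot (−0.298), Smpx (−0.050), Tnnt3 (−0.607) and Myom2 (−0.706) in jak3i, along with the medians of fat cell (−0.565) and endothelial genes (−0.543) in jak1i and of fat cell (−0.559) and bulge genes (−0.056) in jak3i.

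Over the 35 lists in each of the 4 main comparisons camera made 83 calls and 0 with an estimated correlation. Counted apart from these, directional fry made 57 calls and mixed fry 53, and camera without single arrays 78 to 86. Of 957 genes shared by both arms from 0 to 12 weeks, 351 changed at least 2-fold in both, the random block gave 729, leaving out arrays gave 0 to 1089, and the hair shaft and muscle covariates gave 0 and 117.

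Leaving out each array in turn, where a lone array at 24 weeks is assumed to vary like the other groups, gave 13 to 559 genes for jak1i and 69 to 1142 for jak3i against PBS at 6 weeks, 597 to 2940 and 854 to 3547 at 12 weeks and 1470 to 4469 for either inhibitor. At 0 weeks jak3i against PBS gave 0 to 4 and jak1i 0. From 0 weeks, PBS gave 0 to 4 at 6 and 83 to 404 at 12 weeks, jak1i 506 to 2996, 1168 to 2196 and 1 to 468 at 6, 12 and 24 weeks, and jak3i 73 to 2463, 1 to 1886 and 0 to 310. The changes relative to PBS gave 276 to 1916 for jak1i and 0 to 1182 for jak3i, and jak1i against jak3i 0 to 1 at 6 and 24 weeks and 0 at 12 weeks. Of named genes by omission, 702 kept their side of the threshold and 206 lost it, Krtap15 and Krtap26-1 in jak1i against PBS, Sprr1b in jak1i and Krt2 in jak3i from 0 weeks in 6 omissions each.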

Other observations

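The comparisons of 24 with 12 weeks were added after the data had been seen. In jak3i, 6 genes passed the threshold between 12 (n = 3) and 24 weeks (n = 2), all higher. They were the T and NK cell genes Klrd1 2.61 (0.45, 0.0221), Nkg7 2.49 (0.37, 0.0062), Ctsw 2.11 (0.35, 0.0175), Trat1 1.70 (0.22, 0.00209) and Cd3d 1.41 (0.23, 0.0175), and the cadherin gene Cdh17 1.24 (0.21, 0.0175), while 938 genes were under an unadjusted p of 0.05. The cytotoxic list rose in 3 of 21 members over all genes and 15 over the list alone (median 1.47, camera adjusted p = 6.8e-28, adjusted p = 0.0114 with an estimated correlation). T cell genes rose in 2 of 19 and 13 (median 0.71, adjusted p = 0.0114) and MHC class II genes in 0 of 8 and 7 (median 0.90, adjusted p = 0.0450), each p with an estimated correlation. The cytotoxic list mean rose by 1.411 (95% interval 0.752 to 2.070) and the interferon-γ list mean by 1.198 (0.014 to 2.382), with 0 interferon-γ genes past the threshold over all genes. In jak1i 0 genes passed in limma (610 under an unadjusted p of 0.05), and the cytotoxic list mean moved by 0.602 (−0.057 to 1.260). The jak3i count was 1, 8 and 2 without jak3i at 12 weeks replicate 1 to 3, and 0 and 31 without jak3i at 24 weeks replicate 1 and 2, and the jak1i count 3 and 1 without jak1i at 24 weeks replicate 1 and 2.

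The 2 arrays of each inhibitor at 24 weeks lay apart. The cytotoxic list mean was 0.135 and −0.659 in jak1i and 0.865 and −0.406 in jak3i, against group means of 1.105 and 0.506 at 0 weeks and −0.864 and −1.182 at 12 weeks. Replicate 1 of jak3i at 24 weeks thus stood above its 0-week mean. In the same arrays the hair shaft list mean was 0.925 and −3.299 in jak1i and 0.453 and −2.579 in jak3i, and that of stressed keratinocytes 1.485 and −1.465 and 0.522 and −1.586, so the array of each arm with the higher cytotoxic mean was also higher in both. The change from 0 to 24 weeks of that mean was lower in jak1i than in jak3i, by −1.090 (95% interval −2.022 to −0.158), with 8 of 21 members past the threshold over the list alone (camera adjusted p = 7.5e-15, adjusted p = 0.152 with an estimated correlation). For T cell genes it was 6 of 19 (camera adjusted p = 1.1e-16, adjusted p = 0.0763 with an estimated correlation). No gene passed in limma (369 under an unadjusted p of 0.05), 1 gene without jak1i at 24 weeks replicate 1 or 2. The difference starts from unequal values at 0 weeks.

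Hair shaft values were uneven within both inhibitor groups at 6 weeks. The list mean was −2.754, 3.049 and −1.035 in jak1i and 3.670, −2.982 and −2.759 in jak3i, against group means of 1.107 to 2.055 at 0 weeks.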
